A study of Danio rerio with 4 samples.

How the data were processed

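Zebrafish larvae of the AB strain were taken at 4 days post fertilization, dissociated, and sorted by flow cytometry for cells with low cd41:eGFP fluorescence, a gate used for hematopoietic stem and progenitor cells (HSPCs). The cd41 gene is listed as itga2b. About 500 cells entered each library, and cDNA was amplified from them before library construction, per the labels' protocols. The samples formed 2 groups, 2 libraries from siblings and 2 libraries from smu07 mutants. The series title names slc20a1b, a sodium-dependent phosphate transporter gene. The labels number the samples within each group but do not say whether they came from separate clutches or sorts, so p-values measure only the spread between these samples, which may be technical.

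The authors deposited 1 table of TPM values, a transcript abundance scaled by gene length and to the same total in each library, with 30838 rows named by gene symbol and 1 column for each library. Per the submitters' processing notes, FastQC, STAR, featureCounts and DESeq2 were used with the GRCz11 build. The versions and the gene annotation release are not given in the sources used here. TPM divides each count by gene length and then by the library's total, so it keeps no depth and a rise of abundant genes lowers all others. Of the rows, 23029 carried a symbol of the RefSeq annotation of GRCz12tu, and 24698 carried a symbol or synonym. That annotation was used only for names and for which genes neighbour each other.

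Ratios between libraries were used to recover whole reads. In all 23927 of the 23927 rows above 0 in at least 2 libraries, the values were whole multiples of a common step to within a tolerance of 0.0001. The recovered totals were 25102929 and 26598635 reads in the sibling libraries and 28274779 and 29948918 in the mutant libraries. Rows above 0 in only 1 library, 2178 of them, could not be solved and are missing from these totals. On simulated TPM the method returned exactly the simulated counts for 94.5% of 23049 genes and 98.24% of the reads, so totals are slight underestimates. Amplified cDNA reads without molecular identifiers are not independent molecules.

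Genes with a mean of at least 1 TPM over the 4 libraries were tested, 12073 in all. Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with mutant against sibling as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Errors on TPM are SD with n = 2 per group, and errors on log2 differences are standard errors from the model. Data were simulated for 2 sibling and 2 mutant libraries with 12073 genes. Of 100 genes changed 2-fold 33%, and of 100 changed 4-fold 96%, were called in the right direction, and 12 unchanged genes were called. Only these genes and 2 lists were changed in the simulation, against 3443 genes called in the data. The adjusted threshold depends on how many genes change, so these shares and the false calls do not carry over to the data.

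A total of 29 gene lists was written, covering blood lineages, other larval tissues, cell division, stress, signalling and metabolism. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 26 lists tested. Alternatives were an estimated correlation and fry, which asks whether the genes of a list move in 1 direction on balance and does not compare the list with other genes. Camera with an estimated correlation uses only the residual degrees of freedom of the 4 libraries, which by itself raises the p-values. A list that misses the threshold in that form therefore cannot be said to have lost its call through correlated members. The list of mitochondrially encoded mRNAs matched 0 rows and was not analysed here. The pronephros list and the list of liver and exocrine pancreas had 4 measured members each and were not tested. The genes named are slc20a1b with its paralogs, itga2b, myb and runx1, then the 8 largest called changes per direction among genes with a mean of at least 5 TPM, a gene symbol and no overlap between the groups' libraries. They also include up to 4 members with the smallest p of each list past its test, up to 4 called members of any list, and the most abundant marker of each cell type. The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except voom on the recovered reads, the lists of heat shock chaperones, immediate early genes, aryl hydrocarbon receptor targets, lens and photoreceptor genes and chemosensory receptors, and the tests built on them. Also chosen after the data were seen were the recovery of reads and what was computed from it, the summed TPM of lists, and every test of what may lie behind a pattern, including the thinning of reads and the share of calls near slc20a1b.

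The alternatives changed the pseudocount, the filter on low values, the scaling, the limma settings, the list test, the replicate block and the threshold, and left out each library in turn. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other group. The libraries of a pair differed by more than the counting error of reads, with a chi-square of their recovered reads per degree of freedom of 23.9 for the siblings and 15.2 for the mutants. This sets aside only 1 library deposited or sequenced again, and amplification noise alone could give such values, so it does not show that the samples were separate. Reads of near-identical paralogs, such as globins, hsp70 genes, NK-lysins and keratins, may be split between copies. A row named for a microRNA holds reads from a library of amplified cDNA and may reflect its host transcript. Figures and recovery used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.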

Results

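Expression was measured in cd41:eGFP-low cells sorted from 4-day-old zebrafish larvae, in 2 sibling and 2 smu07 mutant libraries of about 500 cells each. The comparison asked how expression in mutant HSPCs differs from that in sibling HSPCs. The recovered depth was 25102929 and 26598635 reads in the sibling libraries and 28274779 and 29948918 in the mutant libraries. The mutant libraries had 23881 and 23978 genes above 0, against 19528 and 19811 in the siblings. The mitochondrial ribosomal RNA mt-rnr2 took 10.1 and 12% of TPM in the mutant libraries and 8.22 and 8.53% in the siblings. On the log2 scale the sibling pair correlated across genes at r = 0.973 and the mutant pair at r = 0.992, against 0.940 to 0.946 between the groups. Genes are not independent replicates.

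The slc20a1b transcript, which encodes a phosphate transporter, stood at 39.3 and 42.4 TPM in the sibling libraries and at 49.3 and 53.8 TPM in the mutant libraries. The log2 difference was 0.33 (SE 0.12, limma, Benjamini-Hochberg adjusted p = 0.0827) and did not pass the test. The labels do not give the kind of lesion, so the transcript level could not check the genotype labels. Its paralogs slc20a1a and slc20a2 lay below 1 TPM in all 4 libraries. The difference in slc20a1b passed the test at 0.43 under median-of-ratios scaling and at 0.56 under quantile normalization.

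Between the groups 3443 of 12073 genes were called, 1196 higher and 2247 lower in the mutant libraries. Of these, 641 were at least 2-fold higher and 530 at least 2-fold lower. The transcript behind the sorting gate, itga2b, an integrin subunit of thrombocytes and progenitors, fell from 58.9 ± 11.4 to 21.4 ± 2.93 TPM (SD, n = 2 per group; log2 difference -1.41, SE 0.18, limma adjusted p = 0.00703). The transcription factor gene runx1, required for the emergence of definitive blood stem cells, rose from 7.6 ± 0.711 to 15.1 ± 0.788 TPM (log2 difference 0.91, SE 0.16, limma adjusted p = 0.0129). The progenitor gene myb stood at 11.4 ± 0.711 and 11.6 ± 3.88 TPM, with overlapping libraries. The share of calls that were lower was 65.3%. It was 54.2% under median-of-ratios scaling (1397 higher, 1656 lower) and 51.1% under quantile normalization (1329 higher, 1390 lower). With no filter on low values it was 46.0% (1321 higher, 1124 lower), and with at least 5 and 20 TPM it was 73.8% and 78.0%. The number of calls rested on the mutant pair: without mutant replicate 1 only 3 genes were higher and 8 lower, and without mutant replicate 2 only 0 and 4, while 2879 and 3116 genes had an unadjusted p under 0.05. Of the genes named here, the call then held for il13, hsp70l and hsp70.3 in both cases. Without sibling replicate 1 the counts were 1855 and 3219, and without sibling replicate 2 they were 2178 and 2934.

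**Figure D1:**
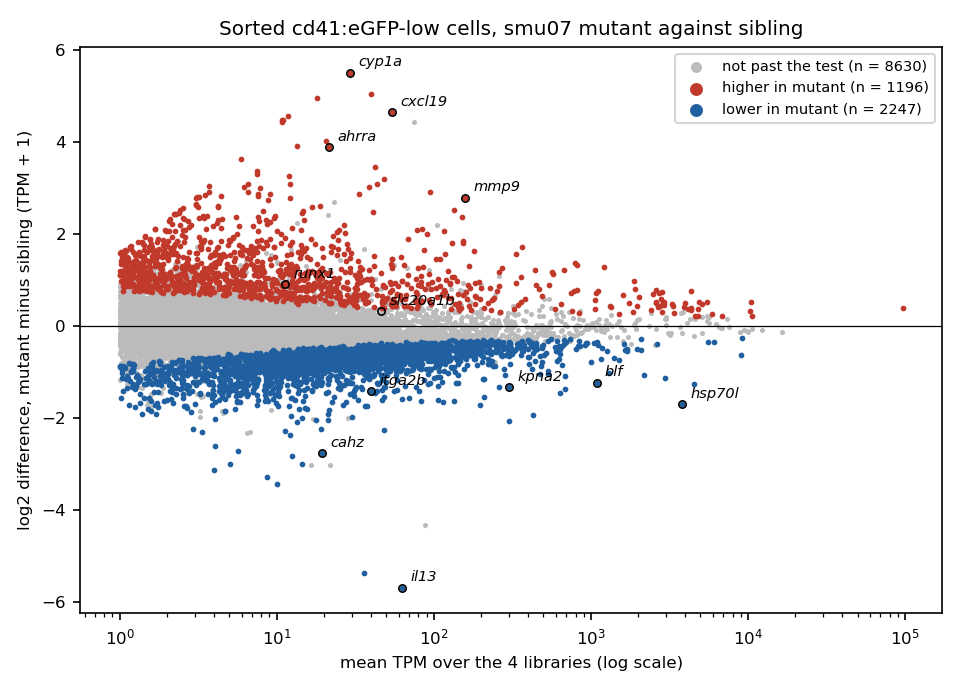
Log2 difference (mutant minus sibling, on TPM + 1) of each tested gene against its mean TPM over the 4 libraries on a log axis. Red points are the 1196 genes called higher, blue points the 2247 called lower and grey points the genes that did not pass, and il13 at -5.69 and cyp1a at 5.51 are the outermost named genes.

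Transcripts of the thrombocyte and erythroid lineages were lower in the mutant libraries. Of 14 measured thrombocyte genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median log2 difference of -0.93. They included gp1bb, a von Willebrand factor receptor subunit (121 ± 7.96 to 53 ± 5.47 TPM), the transcription factor gene nfe2 (65.8 ± 9.65 to 28.5 ± 0.638 TPM) and blf (1526 ± 157 to 655 ± 141 TPM). The list passed its test (camera adjusted p = 0.0037), with an adjusted p = 0.47 with an estimated correlation. Of 20 erythroid genes, 11 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.00168, adjusted p = 0.407 with an estimated correlation). The carbonic anhydrase gene cahz fell from 34.5 ± 10.2 to 4.14 ± 0.372 TPM, the anion exchanger gene slc4a1a from 173 ± 21.1 to 55.6 ± 17.4 TPM, and the heme pathway genes blvrb and urod by 1.16 and 0.81 on the log2 scale. The embryonic globin hbbe1.1, whose reads may be shared with other globins, read 768 and 231 TPM in the siblings and 76.9 and 128 TPM in the mutants, and its log2 difference ranged from -2.94 to -1.21 as 1 library was left out. With genes of at least 20 TPM only, the thrombocyte and erythroid lists no longer passed (adjusted p = 0.287 and 0.088).

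Among 26 HSPC regulators 5 rose, 7 fell and 14 did not pass (7 and 9 adjusted over the list alone). The erythroid and stem cell factor gene tal1 fell from 145 ± 12.4 to 66.3 ± 1.56 TPM and gfi1b from 27.5 ± 1.65 to 15.8 ± 1.32 TPM, whereas csf1rb and the myeloid factor gene cebpa rose by 0.53 and 0.50 on the log2 scale. The rise of cebpa was 0.32 and did not pass without sibling replicate 1. The list did not pass (camera adjusted p = 0.587). Its median was -0.019 and its mean -0.093, whereas the test, which compares it with other genes, pointed upward. Of 16 lymphoid genes 7 fell and 1 rose (also 7 and 1 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0857). It passed without sibling replicate 1 (0.0218), without sibling replicate 2 (0.0373), under quantile normalization (0.0266), with no filter (0.00395) and with fry (0.0478), which does not compare a list with other genes. Over all alternatives its adjusted p ranged from 0.00395 to 0.711, and it was 0.711 with at least 5 TPM, 0.407 with an estimated correlation, 0.167 without mutant replicate 2 and 0.103 with voom. The chemokine receptor gene cxcr4b fell from 928 ± 102 to 337 ± 4.08 TPM, the T cell kinase gene zap70 from 7.16 ± 2.59 to 0.989 ± 0.353 TPM and gata3 by 1.1 on the log2 scale, and runx3 rose by 0.80. The most abundant lymphoid marker, ccr9a, stood at 650 ± 114 and 794 ± 22.7 TPM, and passed without sibling replicate 1 (log2 difference 0.48) and with voom (0.38).

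Macrophage transcripts were higher in the mutant libraries. Of 18 measured genes 12 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 difference of 0.95. The cathepsin gene ctsl.1 rose from 170 ± 27.2 to 561 ± 4.32 TPM, the chemokine gene ccl34b.1 from 8.82 ± 1.71 to 37.0 ± 3.60 TPM, and mfap4 from 87.0 ± 5.66 to 166 ± 12 TPM. The list passed (camera adjusted p = 3.85e-06). With an estimated correlation its camera adjusted p was 0.407, although the estimate of -0.0080 lay below the preset 0.01. That form has few residual degrees of freedom, so the higher value is no evidence of correlated members. Of 15 neutrophil genes 6 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.000641, adjusted p = 0.407 with an estimated correlation). Its call ended with no filter on low values (adjusted p = 0.0574), and its summed TPM was 7462 and 7559 in the siblings and 7072 and 6841 in the mutants. Most of that sum was cebpb, at 6150 and 6338 TPM in the siblings and 5182 and 4681 in the mutants. The share of recovered reads on the list was 1.02 to 1.05 times higher over the mutant-sibling pairs. The gelatinase gene mmp9 rose from 40.6 ± 15.7 to 278 ± 34.3 TPM and cfl1l from 4.11 ± 2.15 to 15.3 ± 3.72 TPM. In contrast, cebpb, a transcription factor gene and the most abundant member, fell from 6244 ± 133 to 4932 ± 355 TPM, and srgn fell by 0.68 on the log2 scale. The fall of cebpb did not pass without sibling replicate 1 (-0.36) or without sibling replicate 2 (-0.32).

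Of 23 genes of the NF-kB and inflammation list 8 rose and 3 fell (9 and 4 adjusted over the list alone), with a median of 0.69. The cytokine gene tnfb rose from 362 ± 54.0 to 794 ± 35.4 TPM and the acute phase gene saa from 6.92 ± 1.3 to 21.1 ± 0.413 TPM. The feedback inhibitor genes socs3a and tnfaip3 rose by 0.90 and 0.77 on the log2 scale. The list passed (camera adjusted p = 0.000641), with an adjusted p = 0.47 with an estimated correlation. The same mutant libraries held more keratinocyte transcript, with summed marker levels of 325 and 216 TPM against 78.1 and 89.2 TPM in the siblings. The summed macrophage markers were 2805 and 2632 TPM in the mutants and 1379 and 1528 TPM in the siblings.

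Genes of cell division were lower in the mutant libraries. Of 39 measured G2/M and mitosis genes 23 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 1.39e-06, adjusted p = 0.407 with an estimated correlation). The nuclear import gene kpna2 fell from 431 ± 2.44 to 172 ± 7.20 TPM, the spindle gene tacc3 from 45.7 ± 0.166 to 17.2 ± 0.921 TPM, the topoisomerase gene top2a from 49.5 ± 7.17 to 19.1 ± 1.15 TPM and the mitotic kinase gene aurka from 64.1 ± 0.746 to 30.3 ± 5.07 TPM. Of 40 G1/S and DNA replication genes 16 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.32. The sliding clamp gene pcna fell from 1372 ± 84.4 to 979 ± 17.6 TPM, cdc45, rpa2 and rrm1 fell by 0.96, 0.51 and 0.58 on the log2 scale, and the cyclin gene ccne2 rose from 11 ± 0.262 to 26.9 ± 1.41 TPM. This list passed narrowly (camera adjusted p = 0.0246, adjusted p = 0.407 with an estimated correlation). It no longer passed without sibling replicate 1 (adjusted p = 0.124), under quantile normalization (0.437) or median-of-ratios scaling (0.0623), without the trend (0.0537) or with genes of at least 5 TPM (0.272) or 20 TPM (0.411) only. The cell type markers differed in the same libraries. Summed thrombocyte TPM was 2182 and 2064 in the siblings and 977 and 1136 in the mutants. Most of this sum was blf alone, at 1637 and 1414 TPM in the siblings and 555 and 755 in the mutants. Summed erythroid TPM was 2080 and 1615 against 828 and 948, and the log2 ratio of the summed macrophage means was 0.90. Expression changes within cells were not separated from a changed mix of cells.

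Nucleotide synthesis and ribosome assembly genes were lower, and ribosomal protein genes higher. Of 19 purine and pyrimidine synthesis genes 10 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.000307, adjusted p = 0.407 with an estimated correlation). The guanine nucleotide enzyme gene impdh2 fell from 149 ± 0.662 to 68.9 ± 4.09 TPM, the pyrimidine enzyme gene dhodh from 62.8 ± 0.260 to 25.7 ± 1.17 TPM, and prps1a and ctps1a by 0.89 and 0.74 on the log2 scale. The summed TPM of the list was 3598 and 3625 in the siblings and 3944 and 3195 in the mutants. Of 35 ribosome biogenesis genes 19 fell and 1 rose (also 19 and 1 adjusted over the list alone), among them wdr43 (317 ± 24.7 to 174 ± 0.887 TPM) and utp15 (96.1 ± 9.77 to 49.0 ± 2.09 TPM), with a median of -0.39 (camera adjusted p = 0.000852, adjusted p = 0.407 with an estimated correlation). With genes of at least 20 TPM only, the ribosome biogenesis list no longer passed (adjusted p = 0.159). Of 73 ribosomal protein genes 38 rose and 2 fell (41 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.27e-12, adjusted p = 0.407 with an estimated correlation). They included rps25 (2122 ± 1.94 to 3531 ± 63.6 TPM) and rpl27a (1391 ± 6.52 to 2438 ± 166 TPM), and the group took 267279 and 259031 TPM in the siblings and 304640 and 289265 TPM in the mutants. None of the 13 lists past the test changed direction under the 3 scaling alternatives, but the G1/S, muscle, and fibroblast and cartilage lists lost their calls under quantile normalization and the G1/S list under median-of-ratios scaling.

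**Figure D2:**
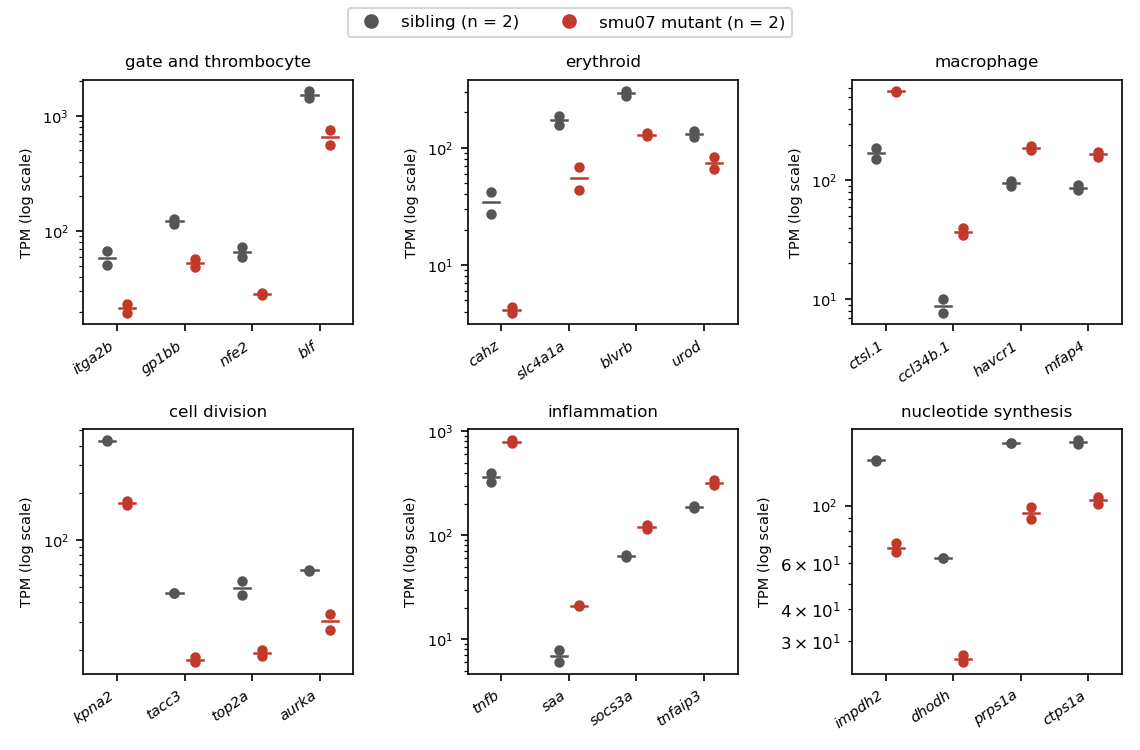
TPM of named genes in each library on a log axis, grouped by gene list, with sibling libraries in grey and mutant libraries in red; each point is 1 library and each bar the mean of 2. The libraries of the groups do not overlap for any gene shown, for example itga2b at 50.8 and 66.9 TPM in the siblings and 23.5 and 19.3 TPM in the mutants.

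Markers of cell types outside the blood were also measured. Of 10 keratinocyte genes 8 rose and 0 fell (also 8 and 0 adjusted over the list alone), with a median of 2.44 (camera adjusted p = 3e-05, adjusted p = 0.407 with an estimated correlation). Their most abundant member, icn, rose from 35.4 ± 11.1 to 146 ± 46.5 TPM and the keratin genes cyt1 and cyt1l by 3.32 and 3.09 on the log2 scale, whereas krt91 was listed at 0 in both sibling libraries and at 27.6 and 16.4 TPM in the mutants. Of 8 muscle genes 4 rose and 0 fell (also 4 and 0 adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.407 with an estimated correlation), all near the floor, such as tpma at 0.202 ± 0.12 and 2.34 ± 1.01 TPM. Their most abundant marker, actc1b, stood at 4.11 ± 0.197 and 4.61 ± 0.987 TPM. Of 5 fibroblast and cartilage genes 3 rose and 0 fell (also 3 and 0 adjusted over the list alone; camera adjusted p = 0.0213, adjusted p = 0.407 with an estimated correlation), including col1a1b by 1.69 and sparc by 1.71 on the log2 scale, and col1a2 was listed at 0 in both siblings. Their most abundant marker, twist1a, read 0.886 and 23 TPM in the siblings and 5.09 and 3.75 TPM in the mutants (log2 difference -0.32), and moved between -2.16 and 1.51 as 1 library was left out. The summed TPM of the fibroblast and cartilage markers was 4.21 and 34.2 in the siblings and 27.4 and 18.5 in the mutants. Without sibling replicate 1 the muscle list had an adjusted p of 0.0565 and the fibroblast and cartilage list 0.342, and without mutant replicate 2 the muscle list had 0.246. Under quantile normalization they had 0.0731 and 0.0583. The rise of cyt1l ranged from 2.44 to 3.74 as 1 library was left out.

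Of 11 endothelial genes 2 fell and 2 rose (also 2 and 2 adjusted over the list alone; camera adjusted p = 0.445). The adhesion gene sele fell from 50.1 ± 2.37 to 15.7 ± 0.558 TPM and the water channel gene aqp1a.1 from 46.6 ± 12.9 to 15.5 ± 4.81 TPM, while stab1 rose from 0.917 ± 0.355 to 5.99 ± 0.318 TPM. Of 6 neural genes 1 rose and 1 fell (also 1 and 1 adjusted over the list alone; camera adjusted p = 0.70), with a median of 0.065 and a mean of -0.13. In the untested lists, 3 of 4 pronephros genes and 2 of 4 genes of liver and exocrine pancreas rose, including cdh17 by 1.85 and rbp4 by 1.87 on the log2 scale. The pancreas marker cpa5, which the neutrophil list also holds, stood at 62.9 ± 29.6 and 74.6 ± 7.53 TPM.

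The largest called changes included genes of other functions. Among the rises, the xenobiotic monooxygenase gene cyp1a went from 0.302 ± 0.398 to 58.4 ± 18.8 TPM (log2 difference 5.51, SE 0.31, limma adjusted p = 0.00191), and ahrra, the aryl hydrocarbon receptor repressor gene, from 1.80 ± 0.869 to 41.2 ± 15.1 TPM. The tight junction gene cldnb, the chemokine gene cxcl19 and the leptin gene lepb rose by 5.05, 4.66 and 3.92 on the log2 scale (SE 0.75, 0.85 and 0.51). Their sibling libraries differed, with cxcl19 at 0.493 and 10.2 TPM, and leaving out 1 library moved cldnb between 3.90 and 6.21, cxcl19 between 3.21 and 6.11 and lepb between 3.11 and 4.74. In addition, capsla and smkr1 were listed at 0 in both siblings. Among the falls, the type 2 cytokine gene il13 went from 125 ± 15.7 to 1.43 ± 0.0190 TPM (log2 difference -5.69, SE 0.15, limma adjusted p = 0.000233). The other falls were mir155, nkl.4, mir222, mettl11b, cahz, the IL-33 receptor gene il1rl1 and klf17, by 3.43, 3.29, 2.99, 2.82, 2.76, 2.71 and 2.36 on the log2 scale. The reads at mir155 and mir222 may come from host transcripts, and those of nkl.4 may be shared with paralogs. The sibling libraries read 3.72 and 30.7 TPM for nkl.4, and leaving out 1 library moved its log2 difference between -4.66 and -1.91 and that of mir222 between -3.68 and -2.31. Without mutant replicate 1 the call held for il13 (adjusted p = 0.0217) and ended for the other genes named here, and the same held without mutant replicate 2 (0.0264 for il13).

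The remaining lists did not pass, although some did under an alternative. With no filter on low values these were ER stress (adjusted p = 0.0168), dissociation (0.0422) and oxidative phosphorylation (0.00323). The ERK feedback list passed under quantile normalization (0.037), with voom (0.0407) and with fry (0.0199), the antioxidant list under quantile normalization (0.0454), and the phosphate list without mutant replicate 2 (0.0312). Over all alternatives the adjusted p ranged from 0.0168 to 0.821 for ER stress, 0.0422 to 0.967 for dissociation, 0.00323 to 0.874 for oxidative phosphorylation, 0.0199 to 0.537 for ERK feedback, 0.0454 to 0.747 for antioxidant and 0.0312 to 0.407 for phosphate. In the p53 and apoptosis list 4 of 20 genes rose and 6 fell (also 4 and 6 adjusted over the list alone; camera adjusted p = 0.716), with the apoptosis gene bbc3 rising from 4.24 ± 1.15 to 18.4 ± 0.660 TPM and sesn1 falling by 0.99 on the log2 scale. In the list of ER stress and amino acid response 4 of 25 rose and 10 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.445). Its chaperone genes pdia4 and calr fell by 1.59 and 1.42, and the cystine transporter gene slc7a11 rose from 12 ± 0.618 to 43.7 ± 1.38 TPM. In the dissociation and immediate early list 4 of 24 rose and 8 fell (also 4 and 8 adjusted over the list alone; camera adjusted p = 0.445), with hsp70l falling from 5812 ± 128 to 1794 ± 96.3 TPM. Of 12 interferon genes 3 rose and 1 fell (also 3 and 1 adjusted over the list alone; camera adjusted p = 0.247). Of 16 genes of phosphate and inositol phosphate handling 3 rose, including ip6k2b by 0.62, and 3 fell, including ankhb by 0.74 (also 3 and 3 adjusted over the list alone; camera adjusted p = 0.0857). The ERK feedback list had 3 of 18 higher and 1 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.0644), with spry1 rising from 4.44 ± 1.17 to 25.6 ± 4.37 TPM.

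In the glycolysis list 3 of 25 genes rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.468), with a median of -0.031 and a mean of 0.12. In the antioxidant list 5 of 28 rose, including sqstm1 from 448 ± 114 to 1148 ± 114 TPM, and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.225). Of 76 nuclear encoded genes of oxidative phosphorylation 2 rose and 15 fell (2 and 13 adjusted over the list alone; camera adjusted p = 0.401), uqcrc2b by 0.55 on the log2 scale.

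**Figure D3:**
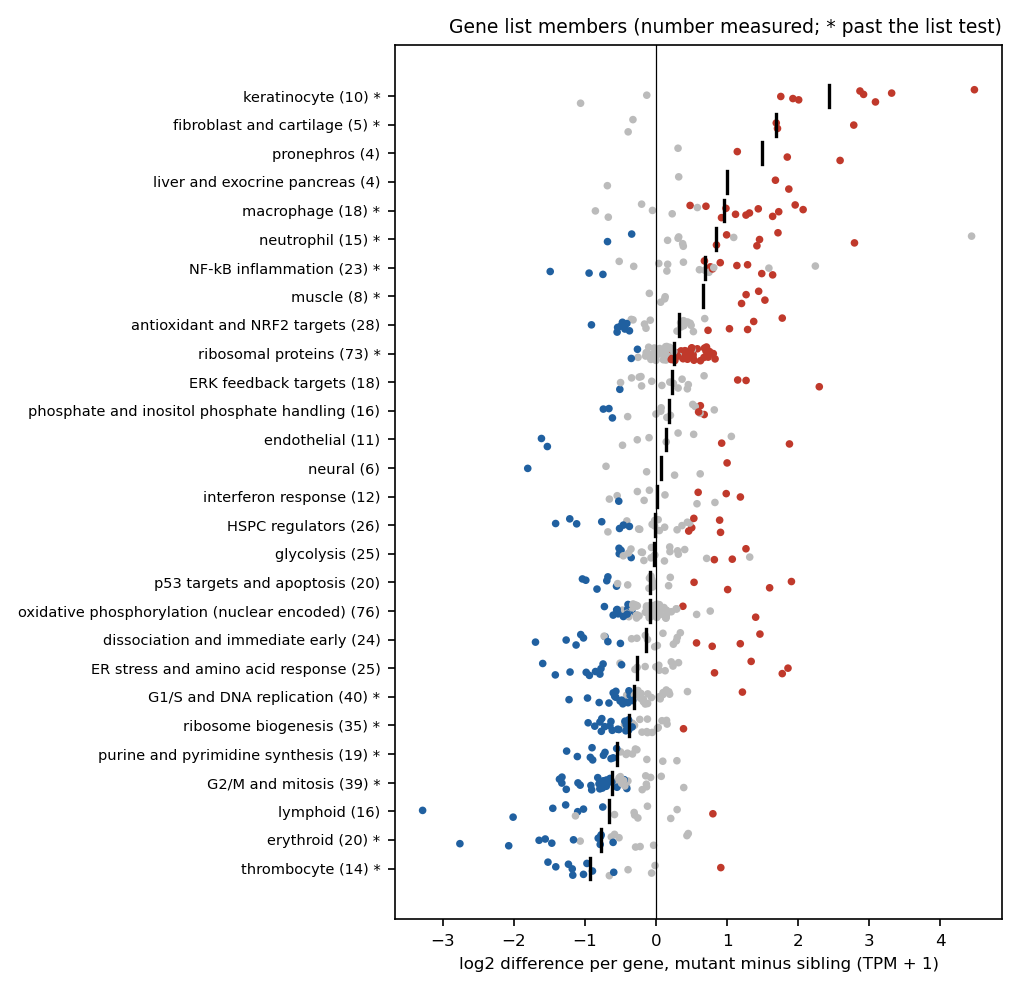
Log2 difference (mutant minus sibling, on TPM + 1) of each measured member of the gene lists, with the number of members in brackets, called genes in red (higher) or blue (lower), others in grey, and the list's median as a black bar. Asterisks mark the 13 lists past the camera test, 7 higher and 6 lower in the mutant libraries.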

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

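Voom on the recovered reads was chosen after seeing the data; the other alternatives were chosen before the data were examined. Over the alternatives 1825 values of named genes kept direction and side of the threshold, 312 lost the call, 9 gained it and 9 reversed, and for gene lists the numbers were 422, 34, 13 and 14. When 1 library was left out, calls ranged from 0 to 2178 higher and from 4 to 3219 lower genes. All 3336 and 3355 measured calls kept their sign without mutant replicate 1 or 2, but they had been called on these same libraries, which makes a kept sign likely. The loss of calls came where the variance rested on the wider sibling pair alone (median SD 0.161 against 0.106 on the log2 scale). Whether that spread caused the loss was not tested. Leaving out a sibling library removed as many samples without such a loss. With no filter, which tested 26105 genes, 1321 were higher and 1124 lower, so most calls were then higher. With at least 5 TPM 778 were higher, and with at least 20 TPM 405 were higher, 1439 lower and 6 lists passed, with fewer genes tested. Quantile normalization gave 1390 lower. With an estimated correlation 0 lists passed camera (smallest adjusted p = 0.407). Yet the estimate was -0.0080 for macrophage, -0.015 for neutrophil and -0.022 for purine and pyrimidine synthesis, below the preset 0.01. The macrophage list's unadjusted camera p still went from 4.45e-07 to 0.0319. Correlated members therefore cannot account for the loss in these lists. The estimated form also uses only the residual degrees of freedom of the 4 libraries, which by itself raises the p-values. In the other lists past camera the estimate ran from 0.024 (G1/S) to 0.356 (thrombocyte). For those lists the test cannot separate correlated members from the few degrees of freedom. With fry, which does not compare a list with other genes and so answers a different question, 9 passed. Of those 9, 7 were also past camera, fry added the lymphoid and ERK feedback lists, and it lost thrombocyte (0.0674), erythroid (0.055), keratinocyte (0.0513), muscle (0.0775), fibroblast and cartilage (0.0775) and NF-kB (0.133). The slc20a1b difference passed at 0.33 with at least 20 TPM, 0.43 with median-of-ratios scaling, 0.56 with quantile normalization and 0.41 with voom. The myb difference changed sign to 0.074 with median-of-ratios, 0.13 with quantile, 0.030 without abundant genes and 0.062 with voom. Over the left-out libraries myb ranged from -0.34 to 0.30, twist1a from -2.16 to 1.51, cpa5 from -0.17 to 0.81 and actc1b from -0.058 to 0.30. Lists not past the test changed direction as follows, as adjusted p: with no filter HSPC regulators 0.581, glycolysis 0.984 and antioxidant 0.747; with at least 5 TPM endothelial 0.62 and p53 0.704; with at least 20 TPM dissociation 0.967 and oxidative phosphorylation 0.544; with median-of-ratios oxidative phosphorylation 0.874; with quantile neural 0.95, p53 0.88 and oxidative phosphorylation 0.439; with fry HSPC regulators 0.0702 and neural 0.055. Glycolysis turned direction without mutant replicate 1 (0.438) and ranged from 0.309 to 0.617 over the left-out libraries. Fewer genes tested and fewer residual degrees of freedom follow from the settings, and no other cause of these changes was tested. The replicate block gave 981 higher and 1682 lower genes and 13 lists. The correlation of deviations between same-numbered libraries was -0.046. With 2 libraries per group this is a single value and cannot show whether such samples shared a clutch, sort or day. Depth is known only through the recovered reads and limits genes near the minimum of 1 TPM most.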

Other observations

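All tests in this part were chosen after the results were seen. Heat shock chaperone transcripts, on a list written after the data were examined, were lower in the mutant libraries: of 27 measured genes 20 fell and 0 rose, with a median log2 difference of -0.80. The inducible chaperone gene hsp70l fell from 5812 ± 128 to 1794 ± 96.3 TPM (SD, n = 2 per group), the cochaperone gene dnaja from 685 ± 53.6 to 178 ± 18.1 TPM and fkbp4 from 204 ± 10.7 to 64.8 ± 1.09 TPM, while hsp90ab1 stood at 2998 ± 46.2 and 3060 ± 20.1 TPM. Of 7 measured aryl hydrocarbon receptor targets 5 rose and 0 fell, among them tiparp from 29.3 ± 3.87 to 128 ± 3.49 TPM and foxq1b from 2.11 ± 0.412 to 8.05 ± 0.990 TPM, and cyp1c1 was listed at 0 in both siblings. Without mutant replicate 1 the limma calls fell to 6 chaperones and 0 receptor targets, and without mutant replicate 2 to 2 and 0, while the medians stayed at -0.83 and -0.81 for the chaperones and 2.07 and 2.11 for the targets.

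The mutant libraries had more genes above 0. Depth alone is argued against, because after thinning every library to the same number of reads the mean difference was 3845 genes, against 4019 before. Both counts leave out the 2178 rows above 0 in only 1 library, whose reads could not be recovered. Free RNA of the whole larva, which would raise every other tissue alike, stays open. In 3 of 7 tissue lists, summed TPM rose in no pair by as much as 50% of the keratinocyte log2 rise of 1.69. These were the endothelial, neural, and lens and photoreceptor lists. In 2 of these 3 the share of reads rose in every pair. The third, endothelial, had sums of 145 and 124 TPM in the siblings and 74.5 and 79.1 in the mutants. In the siblings most of its sum came from sele and aqp1a.1. Their means fell from 50.1 and 46.6 to 15.7 and 15.5 TPM, so this sum may not reflect tissue background. The baseline of each list could also hide a small added share. Background over genes that blood cells are not expected to express may also contribute, since the share of reads on chemosensory receptor genes was at least 2.35 times higher in every mutant-sibling pair, from 92 and 93 reads in the siblings to 243 and 286 in the mutants. A biological difference between the genotypes stays open too, untested.

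For the lower chaperones, scaling between libraries is argued against, since the median of the list was at most -0.72 under median-of-ratios and quantile scaling. A generally weaker response to dissociation, lowering immediate early genes by a like amount, is argued against by their lower quartile of -0.15, above the chaperone median, with 4 of 17 higher and 2 lower. A difference in temperature or handling between the sorts, or an effect of the genotype, may remain, and the labels give no sort batch to separate them.

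For the higher aryl hydrocarbon receptor targets, cells of skin in the mutant sort could bring such transcripts, and the test did not decide: the median rise of the 5 called targets was 39.4 TPM, above the rise of 7 of 8 called keratinocyte markers but below that of icn at 110 TPM. Whether the gate on low cd41:eGFP cells removed skin was not tested. Summed keratinocyte markers stood at 325 and 216 TPM in the mutant libraries and at 78.1 and 89.2 TPM in the siblings. A difference in rearing or exposure and the genotype itself are confounded with the groups, as the labels give no rearing batch.

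A further question was whether calls gathered near slc20a1b, where linked alleles could differ between the groups. Of the 100 measured genes nearest to it in the GRCz12tu annotation 29 were called, against 28.5% of genes elsewhere (one-sided Fisher's exact test, p = 0.496), so the share of calls near this gene was close to that elsewhere. These 100 genes could hold only a small part of the 3443 calls, and effects of linked alleles on genes elsewhere were not tested.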
